A study of Arabidopsis thaliana with 12 samples.

How the data were processed

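Gene expression was measured in roots of 4-week-old Arabidopsis plants on 12 Affymetrix ATH1 arrays, 1 array per sample. The plants were Col-0 (the wild type) and ozs3 (overly zinc sensitive 3, in the Col-0 background), grown in hydroponic culture with 8 h of light and 16 h of dark, and kept at 23 °C or moved to 4 °C for 24 h. Each of the 4 groups held 3 biological replicates, numbered alike in every group. Biotin-labelled cRNA had been prepared from 100 ng of total RNA.

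The authors deposited 1 value per probe set and array, made with RMA (background correction, normalization between arrays and summary of each probe set) per the submitters' processing notes; the RMA version is not given in the sources used here. The deposited values are on the log2 scale, as read from the values themselves, which ran from 2.91 to 15.0 with array medians between 6.99 and 7.20. No pair of arrays was identical, and the closest pair shared 0.0351% of its values exactly. Arrays give no read depth, so their number limits the precision, and probe sets with a mean at or below 5 on the log2 scale (6429, 28.3% of those tested) were treated as dim. Where 1 of 2 compared means of a named gene was at or below 5, the difference may be understated, which was not tested. This holds for HIS1-3, AT4G00670, AT5G45310, AT5G48570, AT2G22590, COR27, MTPA1, UGT78D1, AT5G09570, AT1G10875 and AT2G04050 in at least 1 comparison, and both means of ATSPS4F in Col-0 were below it. No labelled technical batch was found, and the labels do not name the gene mutated in ozs3, so its expression could not be used to check the labels.

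Of 22810 probe sets, 64 Affymetrix controls were left out and 22746 were tested. The probe table named a single gene for 13513 of these, several genes for 503 and no gene for 8730, so that 13356 genes could be named. Loci were matched for 13436 probe sets through a gene table of the TAIR10.1 assembly, which was used only for names and for the order of genes. A gene was represented by its probe set with the highest mean over all arrays, and no named gene had another probe set that moved the opposite way past the threshold.

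The comparisons, the tests, the threshold, the 26 fixed gene lists, the rule for naming genes and most alternatives were chosen before the data were examined. A single group-means model was fitted to all 12 arrays with limma 3.58.1 in R 4.3.3 (lmFit, contrasts and eBayes with 8 residual and 5.42 prior degrees of freedom). Its 5 contrasts were cold against control in each genotype, ozs3 against Col-0 at each temperature, and the interaction, which tests whether the cold response itself differed between genotypes. P-values were adjusted by Benjamini-Hochberg within each contrast over all probe sets, and a probe set was called at an adjusted p under 0.05. Differences are given as log2 values with the moderated standard error from limma (SE), and levels as group means with the standard deviation (SD) of 3 replicates.

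The genes named per contrast are the 10 with the largest rise and the 10 with the largest fall among called probe sets of a single gene in which every array of one group lay above every array of the other (for the interaction, the 10 largest in each direction). To these the rule adds up to 4 members of each gene list with the smallest adjusted p, and COR15A, AT4G28450 (SOF1), CUL4 and ZIP9. CBF1, CBF2, CBF3, RD29A, DDB1A, IRT1 and MTP1 belonged to the rule too but have no named probe set here. Other genes are named only as members of short lists.

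The 26 fixed lists held 469 members, of which 60 had a named probe set: 8 lists had none, 7 had 1 or 2 and are described gene by gene, and 11 had at least 3 and were tested. Lists with no named member included aquaporins, endodermis and suberin, and root tip markers. A planned list of cytosolic ribosomal proteins could not be built from the annotation. A further 21 lists were written from the gene symbols after the annotation was read and before any group comparison was made. Camera (limma) with a preset correlation of 0.01 compared each list with all other genes, adjusted over all lists and contrasts, separately for fixed and added lists. Each list was also tested with a correlation estimated from the data, under which none of the fixed or added list calls held, and with fry. The one-way p of fry tests whether a list's genes move, on balance, in 1 direction, and its mixed p whether they change in either direction; neither compares the list with other genes. For fixed lists, calls adjusted over the list alone are given beside those over all probe sets.

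Whether equal replicate numbers pair the arrays was checked by correlating, across probe sets, the deviations of same-numbered arrays from their group means, before any fits were compared. Every pair exceeded the limit of 0.1 for the cold response in Col-0 (0.195, 0.249 and 0.273), for ozs3 against Col-0 at 23 °C (0.294, 0.326 and 0.473) and at 4 °C (0.291, 0.198 and 0.353). The pairing thus comes from the values, since the labels give only shared numbers. The model chosen beforehand has no block, so counts, SEs and calls below ignore this pairing unless the block is named.

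The alternatives tried were the replicate number as a block, an intensity trend with robust moderation, array weights, only the arrays compared, no dim probe sets, no probe sets named s_at or x_at, a repeated quantile normalization, 1 common median for all arrays, and leaving out each array. The fit without s_at and x_at probe sets says nothing about AT2G41730 and AT3G32030, which are represented by such probe sets. For lists they were the estimated correlation, fry, the mean over a gene's probe sets, the block, no dim genes and leaving out each array. The model was tested on simulated data with the size and spread of these arrays: it recovered 92.5% to 95.5% of changes of 1 log2 unit in the contrasts between 2 groups and 79.1% in the interaction, and for changes of 0.5 between 49.3% and 64.2% and 14.9%. It made between 7 and 13 false calls among 22546 unchanged probe sets of 22746. Far fewer probe sets were thus changed in the simulation than were called in the real cold response. At an adjusted p under 0.05 the false calls allowed grow with the number of calls. The false calls and recovered shares therefore hold for the simulated number of changes only. In a list of 14 genes simulated to shift by 0.5, camera with either correlation and fry each detected the shift. The simulated noise was independent between genes and between arrays. The simulation therefore does not test the list tests, or the replicate numbers, at the correlation present in the real data.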

Results

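Roots of Col-0 and ozs3 plants were profiled at 23 °C and after 24 h at 4 °C, with 3 biological replicates in each of the 4 groups. Within groups the arrays correlated at r between 0.994 and 0.997 across probe sets, which are not independent replicates. The first principal component held 73.2% of the variance and separated the temperatures, and the next 2 held 7.28% and 6.29%. Below, levels are log2 intensities as mean ± SD (n = 3 arrays), differences are log2 values ± SE, and adjusted p-values come from limma with Benjamini-Hochberg correction.

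The first comparison asked how wild-type roots responded to cold. COR15A, which encodes a cold-protective chloroplast protein, rose 49.7-fold in Col-0, from 5.04 ± 0.35 to 10.68 ± 0.25 (difference 5.64 ± 0.46, adjusted p = 3.57e-07). AT1G68500 rose by 5.06 ± 0.58, the UDP-glycosyltransferase genes AT2G22590 and AT2G16890 by 4.58 ± 0.21 and 3.98 ± 0.29, and the pectin methylesterase inhibitor family genes AT5G62360 and AT3G17130 by 4.34 ± 0.21 and 4.32 ± 0.29. COR15B, AT4G30650 (a low temperature and salt responsive family), AT5G20790 and the dehydrin gene LTI30 rose by 4.01, 4.14, 3.97 and 3.92. HIS1-3, a stress-inducible linker histone, fell from 8.49 ± 0.55 to 4.34 ± 0.23, which is in the dim range, so the fall may be understated (difference −4.15 ± 0.27, adjusted p = 5.58e-08). AT1G67910 fell by 3.44 ± 0.14, the small heat shock protein gene AT1G54050 fell by 3.32 ± 0.36, and AT5G45310, AT4G31020, AT3G26510, AT4G00670, AT3G48450, AT2G36690 and AT2G25590 changed by between −2.85 and −2.77.

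Among the fixed gene lists in Col-0, all 7 named members of the cold-regulated genes rose in the cold, and all 7 were also called when adjusted over the list alone. They included COR27 (3.86 ± 0.25), COR47 (1.82 ± 0.15), a dehydrin, and STZ (1.49 ± 0.24), a zinc finger repressor. The list median was 3.86 (camera adjusted p = 6.23e-06, and adjusted p = 0.431 with an estimated correlation). Of 14 ribosome biogenesis genes 12 rose, 12 adjusted over the list alone, with a median of 0.64 (camera adjusted p = 1.39e-06, and adjusted p = 0.431 with an estimated correlation). YAO rose by 1.35 ± 0.07, AT3G15460 by 1.42 ± 0.09 and AT4G28450, the SOF1 gene, by 0.64 ± 0.11. In an added list of 29 further ribosome biogenesis genes, 26 rose, among them AT3G10530 (1.64 ± 0.09), and the median was 0.80 (camera adjusted p = 4.31e-13, and adjusted p = 0.195 with an estimated correlation).

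Of the 3 named zinc homeostasis genes in Col-0, ZIP9, of the zinc uptake transporter family, fell 5.13-fold, from 9.44 ± 0.42 to 7.08 ± 0.19 (difference −2.36 ± 0.18, adjusted p = 2.14e-07). MTPA1, a zinc transporter gene, fell by 1.97 ± 0.46 (adjusted p = 0.00281). The zinc deficiency regulator gene bZIP19 rose by 0.32 ± 0.11 (adjusted p = 0.0272). The call ended without Col-0 replicate 1 or 2 at 23 °C (adjusted p = 0.0802 and 0.0610) or Col-0 replicate 3 at 4 °C (0.123). The same 3 calls were made adjusted over the list alone, and the list did not pass (camera adjusted p = 0.421). Of 6 iron deficiency genes 3 rose, as also adjusted over the list alone, including AT1G74770 (0.92 ± 0.14) and AT1G18910 (0.50 ± 0.09), and the list did not pass (camera adjusted p = 0.162). PYE, a regulator of iron homeostasis, was the 1 member that fell, by 0.30 ± 0.11 (adjusted p = 0.0374). This call ended without Col-0 replicate 2 or 3 at 23 °C (adjusted p = 0.111 and 0.0979) or Col-0 replicate 3 at 4 °C (0.184). It also ended with only the arrays compared (0.0600), a repeated quantile normalization (0.0559), 1 common median (0.0639) or array weights (0.0757).

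All 3 heat shock genes fell in Col-0, also adjusted over the list alone, with AT5G48570 at −1.97 ± 0.22 and the small heat shock protein gene AT1G53540 at −2.04 ± 0.42 (list camera adjusted p = 0.101). Of 4 redox genes 2 rose and 1 fell, and 2 rose and 2 fell adjusted over the list alone (camera adjusted p = 0.495). NDB2, an external NAD(P)H dehydrogenase of mitochondria, rose by 2.64 ± 0.12 and the glutathione transferase gene GSTU25 by 1.89 ± 0.38, while AT2G21640, a marker of mitochondrial stress, fell by 1.36 ± 0.25. The flavonoid glycosyltransferase gene UGT78D2 rose by 3.03 ± 0.12 and UGT78D1 by 0.62 ± 0.09, 2 of 3 flavonoid genes with either adjustment (camera adjusted p = 0.0791). Of the 3 unfolded protein response genes, the calreticulin gene CRT1b rose by 1.41 ± 0.10 and ATERDJ3B by 0.32 ± 0.09, the same 2 as adjusted over the list alone (camera adjusted p = 0.0791). Among markers of other tissues, the shoot gene RCA fell by 0.62 ± 0.17 while SBPASE (0.10 ± 0.09) and PRK (−0.10 ± 0.17) were not called. Of 3 root hair genes 2 fell, XTH26 (−0.81 ± 0.26) and EXPA18 (−0.92 ± 0.16). These counts were the same adjusted over each list alone. The XTH26 call ended without Col-0 replicate 1 or 3 at 23 °C (adjusted p = 0.0609 and 0.0665) or Col-0 replicate 2 at 4 °C (0.110). Neither the shoot nor the root hair list passed (camera adjusted p = 0.821 and 0.387), and none of 3 cell cycle genes was called with either adjustment (camera adjusted p = 0.964).

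In lists with 1 or 2 named members, the sucrose phosphate synthase gene ATSPS4F rose in Col-0 by 0.72 ± 0.18 and the dehydration gene LEA4-5 by 2.86 ± 0.21, and the defence regulator gene WRKY53 fell by 1.00 ± 0.13. PRH75 (0.23 ± 0.13), the xylem gene GUT2 (−0.26 ± 0.12), the clock gene GI (0.17 ± 0.11) and CUL4 (0.06 ± 0.08), the scaffold of a ubiquitin ligase, were not called. However, GUT2 was called without Col-0 replicate 3 at 4 °C (adjusted p = 0.0173, with up to 0.451 for other arrays left out) and PRH75 with the replicate number as a block (0.0440). Among the added lists, 18 of 47 UDP-glycosyltransferase genes rose and 4 fell, with a median of 0.13 (camera adjusted p = 0.0130, and adjusted p = 0.195 with an estimated correlation). Of 10 autophagy genes 7 fell and 1 rose, including ATG8C (−0.94 ± 0.11) and APG8H (−0.77 ± 0.09), with a median of −0.58 (camera adjusted p = 0.0271, and adjusted p = 0.566 with an estimated correlation). Without dim genes the autophagy list did not pass (adjusted p = 0.0824). Of 22 nuclear photosynthesis genes 9 fell, among them CHLM (−1.38 ± 0.10) and LHCB4.1 (−1.57 ± 0.18), with a median of −0.36 (camera adjusted p = 0.0275, and adjusted p = 0.661 with an estimated correlation). That list did not pass without Col-0 replicate 2 at 23 °C (adjusted p = 0.0702) or Col-0 replicate 3 at 4 °C (0.0673).

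Over all probe sets, 9987 were called in Col-0, 4649 higher and 5338 lower in the cold, and 1992 of them changed at least 2-fold. With 1 common median for all arrays 52.4% of the calls were higher, against 46.6%. They included 5482 named genes. All 3 cold arrays lay on one side of all 3 control arrays for 52.1% of probe sets, where chance gives 10%. With the replicate number as a block 10786 were called, with 9969 of the 9987 among them.

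The second comparison repeated the cold treatment in ozs3. COR15A rose 42.3-fold, from 6.02 ± 1.36 to 11.42 ± 0.16 (difference 5.40 ± 0.46, adjusted p = 3.87e-07). AT5G20790, COR15B, COR27 and AT1G68500 rose by 4.99 ± 0.39, 4.77 ± 0.31, 4.62 ± 0.25 and 4.49 ± 0.58. AT1G16850, AT2G16890, AT2G22590, AT3G17130 and AT3G55580, of the RCC1 family, rose by between 3.90 and 4.12. AT2G25590 fell 16.0-fold, from 9.28 ± 0.14 to 5.28 ± 0.25 (adjusted p = 3.93e-10), HIS1-3 fell by 3.45 ± 0.27, AT4G00670 fell by 3.28 ± 0.15 and AT1G67910 fell by 3.24 ± 0.14. AT4G29890, AT1G80180, AT2G36690, AT1G54050, the terpene synthase gene AT3G29410 and AT3G29970 changed by between −3.09 and −2.87.

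All 7 cold-regulated genes rose in ozs3, also adjusted over the list alone, with a median of 2.64 (camera adjusted p = 2.86e-05, and adjusted p = 0.431 with an estimated correlation). AT4G33980 rose by 2.64 ± 0.19 and STZ by 2.39 ± 0.24. In ozs3 replicate 3 at 23 °C these 7 genes stood a median of 1.23 above the mean of the other two arrays of the group, with COR15A at 7.60, against 5.24 and 5.23. In that array the 3364 probe sets that rose in both genotypes stood a median of 0.02 above the others. Without that array the rise of COR15A in ozs3 was 6.19 and that of COR15B 5.28. Outside the list, AT1G68500, AT5G20790 and AT1G16850 also varied widely in ozs3 at 23 °C, with SDs of 1.76, 1.08 and 0.99. Their SDs in Col-0 at 23 °C were 0.49, 0.15 and 0.24. AT2G22590 did not vary so (0.22 in ozs3 and 0.23 in Col-0). Which array these SDs rest on was not examined.

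Of the ribosome biogenesis genes, 10 of 14 rose in ozs3 and 11 adjusted over the list alone, with a median of 0.45 (camera adjusted p = 9.19e-04, and adjusted p = 0.431 with an estimated correlation). YAO rose by 1.45 ± 0.07 and AT5G38720 by 1.35 ± 0.09. In the added list of 29, 25 rose and 1 fell, with a median of 0.82 (camera adjusted p = 1.09e-08, and adjusted p = 0.195 with an estimated correlation). All 4 redox genes rose in ozs3, also adjusted over the list alone, with a median of 1.91 (camera adjusted p = 0.0271, and adjusted p = 0.517 with an estimated correlation). GSTU25 rose by 3.83 ± 0.38, NDB2 by 2.45 ± 0.12, AT2G21640 by 1.37 ± 0.25 and AT5G09570 by 0.37 ± 0.13. The AT5G09570 call ended without ozs3 replicate 1 or 3 at 23 °C (adjusted p = 0.0697 and 0.0912) or ozs3 replicate 1 or 2 at 4 °C (0.110 and 0.0805), and with a repeated quantile normalization (0.0632) or array weights (0.0609).

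ZIP9 fell in ozs3 by 1.47 ± 0.18, bZIP19 rose by 0.64 ± 0.11 and MTPA1 was not called (−0.05 ± 0.46), the same calls as adjusted over the list alone (camera adjusted p = 0.934). The zinc list median was −0.05, and 0.08 with 1 common median. Of the 6 iron deficiency genes 5 rose, also adjusted over the list alone, including PYE (0.52 ± 0.11) and AT1G74770 (0.80 ± 0.14). That list did not pass (camera adjusted p = 0.0636). It passed without Col-0 replicate 2 at 23 °C (adjusted p = 0.0483), ozs3 replicate 3 at 23 °C (0.0475) or ozs3 replicate 3 at 4 °C (0.0481). BZIP60, an unfolded protein response transcription factor gene, rose by 1.14 ± 0.12 and CRT1b by 0.44 ± 0.10, and LEA4-5 rose by 3.87 ± 0.21. Among added lists, 16 of 27 expansin and XTH genes, which act on the cell wall, rose and 6 fell, with a median of 0.43 (camera adjusted p = 0.0167, and adjusted p = 0.566 with an estimated correlation). EXLA2 rose by 3.40 ± 0.13 and XTH20 by 2.47 ± 0.15, while XTH26 fell by 1.83 ± 0.26. Of 47 UDP-glycosyltransferase genes 20 rose and 4 fell, with a median of 0.17 (camera adjusted p = 0.0166, and adjusted p = 0.195 with an estimated correlation). Of 15 defensin genes 6 rose, among them PDF2.1 (3.79 ± 0.47) and LCR69 (2.09 ± 0.15), with a median of 0.30 (camera adjusted p = 0.0162, and adjusted p = 0.195 with an estimated correlation).

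In ozs3, 11624 probe sets were called, 5674 higher and 5950 lower in the cold, 2560 of them at least 2-fold, and they included 6489 named genes. All cold arrays lay on one side of all control arrays for 58.4% of probe sets, where chance gives 10%. With 1 common median for all arrays, 14020 were called and the share called higher went from 48.8% to 66.1%. The median of all probe sets moved by 0.13, from 0.05 to 0.18, and the small shifts of list medians here are to be read against that.

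**Figure D1:**
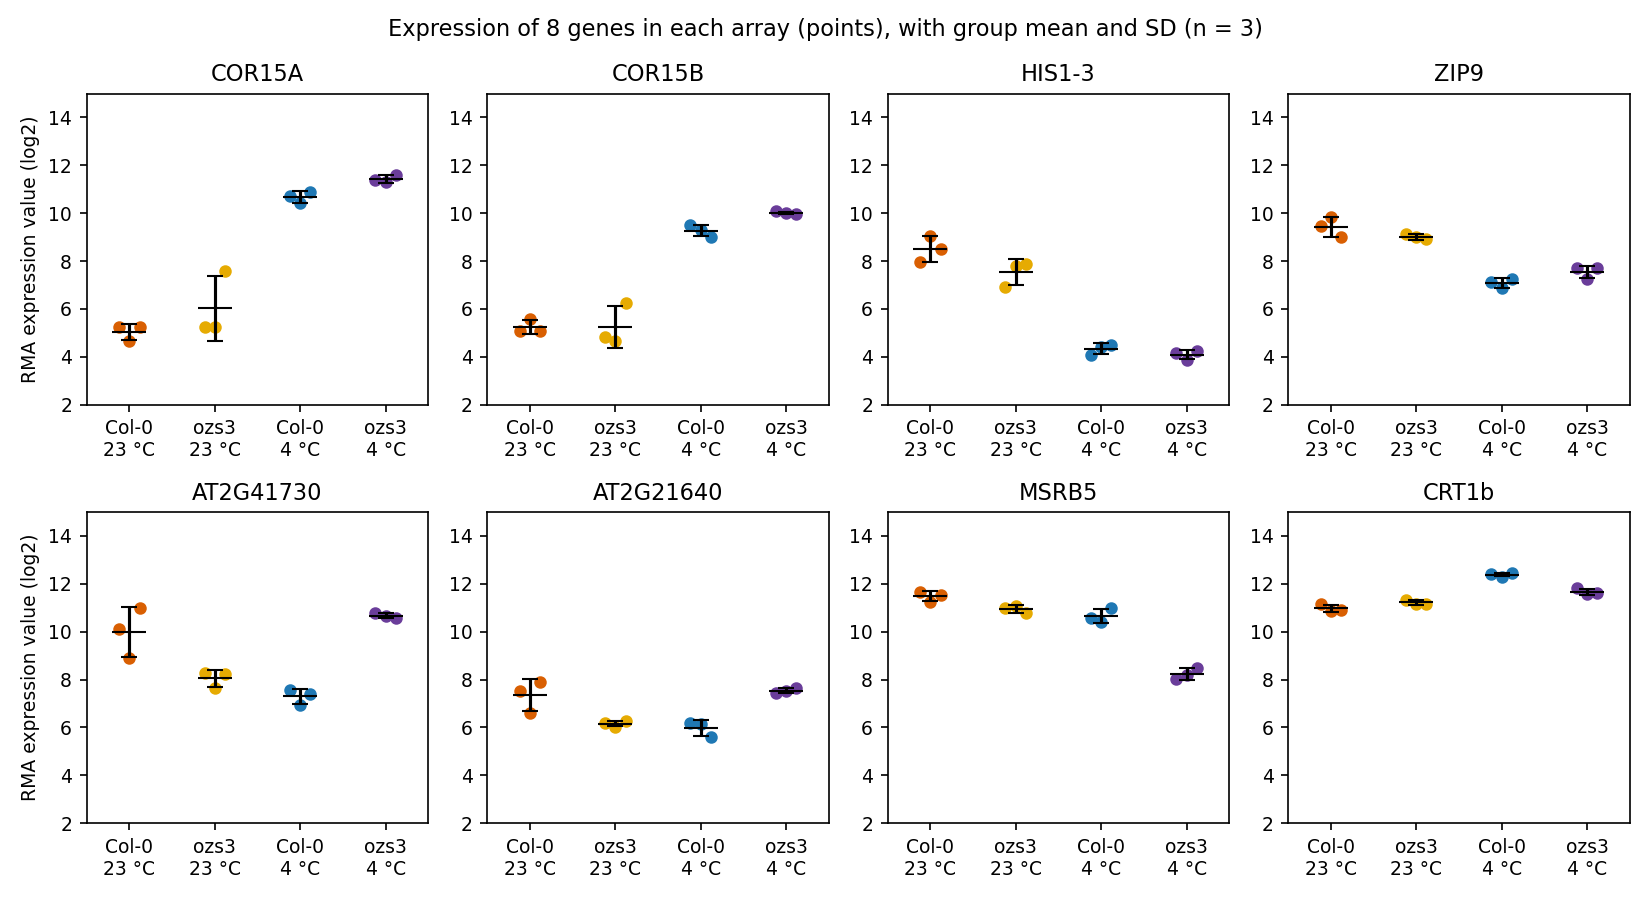
Expression of 8 genes (RMA value, log2) in each array of the 4 groups, with points for arrays and bars for the mean and SD (n = 3). COR15A lies between 10.41 and 11.60 in the 6 cold arrays, and AT2G41730 has a mean of 7.30 in Col-0 and 10.67 in ozs3 at 4 °C.

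The cold responses of both genotypes were set side by side. Of the called probe sets, 7532 changed in the same direction in both genotypes, 3364 higher and 4168 lower, where independent lists would share 1160 and 1396. Opposite calls were made for 154 probe sets, where 2548 would be shared by chance. Across probe sets, which are not independent replicates, the changes in ozs3 had a slope of 0.93 on those in Col-0 (r = 0.84).

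**Figure D2:**
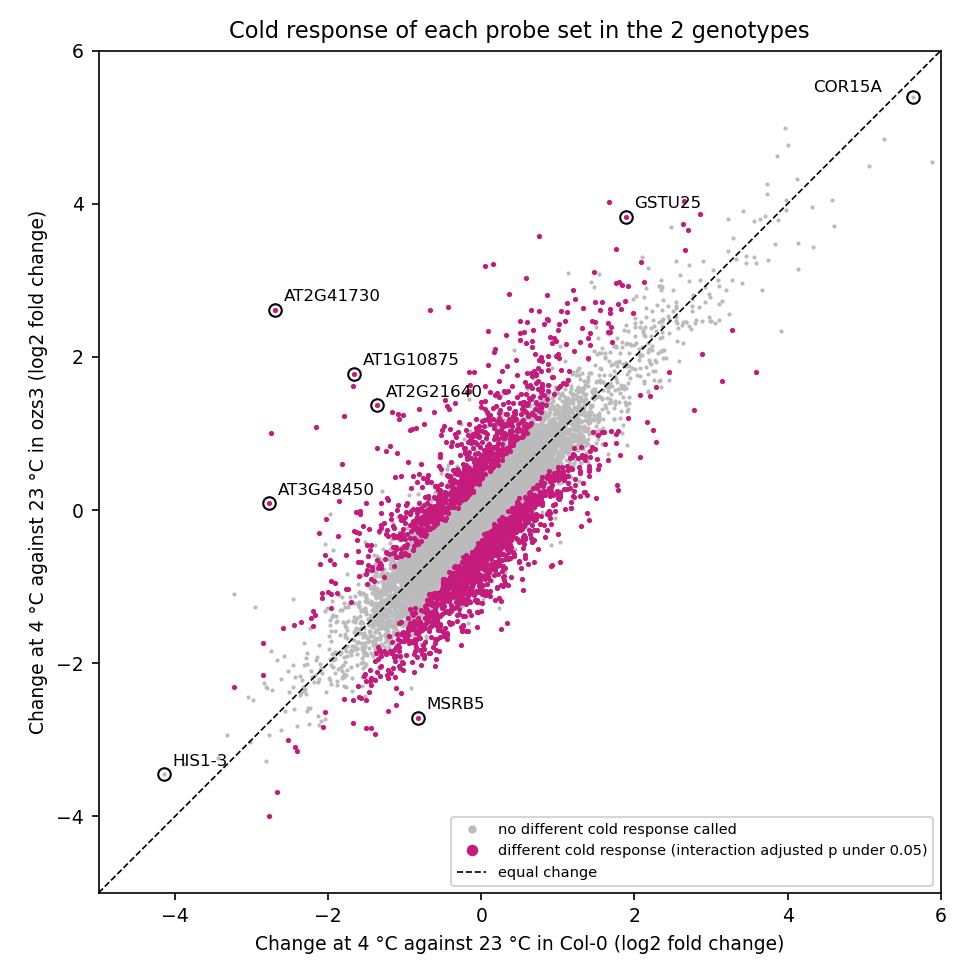
Change in the cold of each probe set (log2 fold change) in Col-0 on the horizontal axis and in ozs3 on the vertical axis, with the 2300 probe sets of the interaction coloured and the dashed line marking equal change. COR15A and HIS1-3 lie near the line, while AT2G41730 changed by −2.69 in Col-0 and by 2.62 in ozs3.

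The third comparison asked how ozs3 roots differed from wild-type roots without cold. QQS, a gene found only in Arabidopsis and linked to starch, was 8.44-fold higher in ozs3, at 9.19 ± 0.48 against 6.11 ± 0.82 (difference 3.08 ± 0.43, adjusted p = 9.23e-04). The ankyrin repeat genes AT5G50140 and AT3G54070 were higher by 2.14 ± 0.16 and 1.62 ± 0.22, and the histone gene HTB11 and AT3G48080 both by 1.73. AT5G51620, AT3G44840 (a methyltransferase family), AT4G01740 and AT5G43030 were higher by between 1.55 and 1.63. AT3G48450 was 6.49-fold lower, at 8.85 ± 0.23 against 11.55 ± 0.22 (difference −2.70 ± 0.19, adjusted p = 3.54e-06). AT1G10875 was lower (−2.44 ± 0.36), as were AT1G26380 (−2.06 ± 0.24), a berberine bridge enzyme-like gene, and AT3G46480 (−2.01 ± 0.14), an oxygenase gene. The same held for AT2G41730 (−1.94 ± 0.37) and CCOAMT (−1.92 ± 0.22), a methyltransferase of lignin synthesis. AT1G60730, AGL72, AT2G22880 and AT2G22120 differed by between −1.88 and −1.76.

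Of the 7 cold-regulated genes 1 was higher in ozs3 at 23 °C and 1 lower, also adjusted over the list alone (camera adjusted p = 0.846). LTI30 was higher by 1.66 ± 0.40 (adjusted p = 0.0255). That call ended without Col-0 replicate 1 or 2 at 23 °C (adjusted p = 0.0510 and 0.113) or ozs3 replicate 1 at 23 °C (0.0691). It also ended with an intensity trend (0.0996), only the arrays compared (0.0935) or array weights (0.0660). AT4G33980 was lower (−1.23 ± 0.19), and COR15A, which was high in 1 array of ozs3 as given above, was not called (0.98 ± 0.46, adjusted p = 0.253). Neither was STZ (−0.43 ± 0.24, adjusted p = 0.354), except without ozs3 replicate 3 at 23 °C (−0.75, adjusted p = 0.0368). MTPA1 was lower at 5.11 ± 0.49 against 6.81 ± 1.24 (difference −1.69 ± 0.46, adjusted p = 0.0438). Of the 12 arrays left out in turn the call held only without Col-0 replicate 3 at 23 °C or Col-0 replicate 1 at 4 °C (adjusted p between 4.06e-04 and 0.176). The MTPA1 call also ended with an intensity trend (0.130) or only the arrays compared (0.105). ZIP9 (−0.42 ± 0.18, adjusted p = 0.211) and bZIP19 (−0.18 ± 0.11) were not called, so that 1 of 3 zinc genes was lower with either adjustment (camera adjusted p = 0.0791). Without Col-0 replicate 3 at 23 °C that list passed (adjusted p = 0.00680, with up to 0.136 for other arrays left out) and ZIP9 was called (−0.63, adjusted p = 0.0461, up to 0.590). None of the 14 ribosome biogenesis genes was called at 23 °C with either adjustment (median 0.11, camera adjusted p = 0.0572). The list passed without Col-0 replicate 2 (adjusted p = 0.0170) or ozs3 replicate 3 at 23 °C (0.00704). AT2G21640 and AT5G09570, 2 of 4 redox genes with either adjustment, were lower in ozs3 by −1.18 ± 0.25 and −0.56 ± 0.13. The AT2G21640 call ended without ozs3 replicate 2 at 23 °C (adjusted p = 0.0523), and that of AT5G09570 without Col-0 replicate 3 (0.0778) or ozs3 replicate 1 or 3 (0.0722 and 0.0617). The redox list did not pass (camera adjusted p = 0.217) except without Col-0 replicate 2 at 23 °C (0.00866, with up to 0.715 for other arrays left out).

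In an added list of 18 stress signalling genes, 5 were lower in ozs3 at 23 °C and none higher, with a median of −0.28 (camera adjusted p = 0.00254, and adjusted p = 0.195 with an estimated correlation). The transcription factor gene WRKY6 (−0.65 ± 0.14) and the glutaredoxin gene GRX480 (−1.69 ± 0.39) were among them. The WRKY6 call ended without ozs3 replicate 2 at 23 °C (adjusted p = 0.0594, with as low as 0.00273 for other arrays left out), and that of GRX480 without ozs3 replicate 1 or 2 at 23 °C (0.0818 and 0.0611), with an intensity trend (0.0710) or with only the arrays compared (0.0668). Shoot, root hair, cell cycle, flavonoid and heat shock genes gave no call at 23 °C over all probe sets. Of these 1 heat shock gene, AT1G53540, was lower adjusted over the list alone (−1.18 ± 0.42, adjusted p = 0.125 over all probe sets, and 0.0342 without ozs3 replicate 3 at 23 °C, with up to 0.396 for other arrays left out). CUL4 (−0.03 ± 0.08) and AT4G28450 (0.08 ± 0.11) were not called. At 23 °C, 1442 probe sets were called, 720 higher and 722 lower in ozs3, 183 of them at least 2-fold, with 794 named genes. With 1 common median 41.2% of 1515 calls were higher, against 49.9%. All arrays of one genotype lay on one side for 26.0% of probe sets, where chance gives 10%. The count was 767 without ozs3 replicate 2 at 23 °C, 783 without ozs3 replicate 1, and 919 and 954 without Col-0 replicates 2 and 3. With the replicate number as a block it was 2253, with all 1442 among them, and array weights gave 2323.

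The fourth comparison set ozs3 against Col-0 in the cold. AT2G41730 was 10.3-fold higher in ozs3, at 10.67 ± 0.11 against 7.30 ± 0.32 (difference 3.37 ± 0.37, adjusted p = 1.01e-04). The MATE efflux gene AT2G04050 was higher by 2.91 ± 0.55, GSTU25 by 2.02 ± 0.38, the acetyltransferase gene AT2G32020 by 1.96 ± 0.30, the flotillin-like gene AT5G64870 by 1.91 ± 0.22 and NDB4, an external NAD(P)H dehydrogenase of mitochondria, by 1.85 ± 0.09. AT3G10930, AT3G45730 and AT4G33666 were higher by 1.78, 1.75 and 1.73, and QQS by 1.66 ± 0.43 (adjusted p = 0.0186). The QQS call ended without Col-0 replicate 2 or ozs3 replicate 1 at 4 °C (adjusted p = 0.0722 and 0.0691), and with an intensity trend (0.0680). MSRB5, a methionine sulfoxide reductase gene, was 5.34-fold lower, at 8.23 ± 0.23 against 10.65 ± 0.29 (difference −2.42 ± 0.16, adjusted p = 3.16e-06). AT2G22120 was lower (−2.34 ± 0.14), as were the terpene synthase gene AT3G29410 (−2.15 ± 0.18) and the methyltransferase family gene AT1G68040 (−1.98 ± 0.22). The oxygenase genes AT1G80320, AT1G52790 and AT1G52820 differed by −1.87, −1.86 and −1.46, and AGL72, the sugar transporter family gene AT1G54730 and AT3G29970 by −1.79, −1.51 and −1.49.

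Of the 7 cold-regulated genes COR27 alone was called at 4 °C with either adjustment (0.87 ± 0.25 higher in ozs3, adjusted p = 0.0347; list camera adjusted p = 0.217). That call of COR27 ended without any 1 of the 6 arrays at 4 °C (adjusted p between 7.36e-04 and 0.125 over all arrays left out), and with an intensity trend (0.0555). COR15A and COR15B were higher in ozs3 by 0.75 ± 0.46 and 0.74 ± 0.31 without a call (adjusted p = 0.318 and 0.135). Without ozs3 replicate 3 at 23 °C, which enters the estimate of the spread, both were called at these differences (adjusted p = 0.00890 and 0.00469, with up to 0.537 and 0.310 for other arrays left out), and the list passed (camera adjusted p = 0.0178, up to 0.412). Both were also called with only the arrays compared (0.00843 and 0.00540), as was STZ (0.47 ± 0.24, adjusted p = 0.00998, against 0.222 with all arrays). Of the redox genes GSTU25 and AT2G21640 (1.55 ± 0.25) were higher in ozs3, 2 of 4 with either adjustment, and the list did not pass (camera adjusted p = 0.0969) except without Col-0 replicate 2 at 23 °C (0.0483, with up to 0.166 for other arrays left out). Of the 3 unfolded protein response genes BZIP60 was higher by 0.75 ± 0.12, and CRT1b (−0.72 ± 0.10) and ATERDJ3B (−0.39 ± 0.09) were lower, the same calls as adjusted over the list alone (camera adjusted p = 0.421). The root hair gene XTH26 was lower (−1.28 ± 0.26) while EXPA7 (0.55 ± 0.18) and EXPA18 (−0.04 ± 0.16) were not called, and adjusted over the list alone EXPA7 was higher too (camera adjusted p = 0.749). EXPA7 was also called over all probe sets without replicate 2 of Col-0 or ozs3 at 23 °C (adjusted p = 0.0498 and 0.0461), Col-0 replicate 1 at 4 °C (0.0376) or ozs3 replicate 2 at 4 °C (0.0285), with the replicate number as a block (5.70e-04), without dim probe sets (0.0474) and with 1 common median (0.0410). UGT78D1, 1 of 3 flavonoid genes with either adjustment, was lower (−0.63 ± 0.09); that list's median was 0.05 (−0.01 with a repeated quantile normalization) but its mean −0.18 and its camera direction was down (adjusted p = 0.423). ZIP9 (0.47 ± 0.18, adjusted p = 0.101) was called only without Col-0 replicate 2 or 3 at 23 °C (adjusted p = 0.0498 and 0.0454). MTPA1 (0.23 ± 0.46), CUL4 (−0.17 ± 0.08) and AT4G28450 (−0.02 ± 0.11) were not called. No shoot, cell cycle or heat shock gene was called either, except that the heat shock gene AT5G48570 was called with the replicate number as a block (adjusted p = 0.0132).

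Of 69 plastid-encoded genes 3 were higher in ozs3 at 4 °C and none lower, with a median of 0.17 (camera adjusted p = 0.00204, and adjusted p = 0.566 with an estimated correlation), among them ccsA (0.51 ± 0.11) and accD (0.42 ± 0.09). The 3 calls are a smaller share than the 1461 of 22746 probe sets called higher, so the shift lies in the median and not in the calls. Of 16 mitochondrially encoded genes 6 were higher, including cox2 (0.76 ± 0.09) and ccb382 (0.68 ± 0.15), with a median of 0.29 (camera adjusted p = 0.00477, and adjusted p = 0.566 with an estimated correlation). Of 27 expansin and XTH genes 5 were higher and 1 lower, with EXLA1 at 1.07 ± 0.14 and EXLA2 at 0.88 ± 0.13 and a median of 0.21 (camera adjusted p = 0.00797, and adjusted p = 0.467 with an estimated correlation). At 4 °C, 3326 probe sets were called, 1461 higher and 1865 lower in ozs3, 180 of them at least 2-fold, with 1794 named genes. With the replicate number as a block the count was 4370, with 3325 of the 3326 among them. All arrays of one genotype lay on one side for 30.8% of probe sets, where chance gives 10%. With 1 common median for all arrays, 60.7% of 3672 calls were higher, against 43.9%.

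The genotype differences at the 2 temperatures were also set side by side. They shared 347 calls in the same direction, 193 higher and 154 lower, where independent lists would share 46.2 and 59.2, and 113 calls were opposite where 105 would be shared by chance. The slope across probe sets was 0.08 (r = 0.07). QQS and AGL72 were called in the same direction at both temperatures, as was AT2G22120. The shared count was 227 without ozs3 replicate 1 at 23 °C, 228 without ozs3 replicate 2 and 551 with the block.

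The last comparison, the interaction, asked which genes responded to cold differently in ozs3. AT2G41730 fell by 2.69 in Col-0 and rose by 2.62 in ozs3 (interaction 5.31 ± 0.52, adjusted p = 1.45e-04). AT2G21640, the marker of mitochondrial stress, fell by 1.36 in Col-0 and rose by 1.37 in ozs3 (interaction 2.73 ± 0.35, adjusted p = 7.08e-04), and AT2G22880, with a VQ motif, moved likewise by −1.17 and 1.28 (interaction 2.45 ± 0.23). AT3G48450 fell by 2.77 in Col-0 and was not called in ozs3 (0.09), with an interaction of 2.86 ± 0.26. Between the genotypes it was called at 23 °C (−2.70) and not at 4 °C (0.16). MSRB5 fell in both genotypes, with −0.83 in Col-0 and −2.71 in ozs3 (interaction −1.88 ± 0.22, adjusted p = 4.50e-04).

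CRT1b had an interaction of −0.97 and BZIP60 of 0.91 ± 0.17, so that 1 of 3 unfolded protein response genes responded more and 1 less in ozs3, and 2 less adjusted over the list alone (camera adjusted p = 0.435). PYE, which fell in Col-0 and rose in ozs3, had an interaction of 0.83 ± 0.16 (adjusted p = 0.00556). ZIP9 fell less in ozs3 (interaction 0.89 ± 0.26, adjusted p = 0.0425). Of the 12 arrays left out in turn, this call held only without Col-0 replicate 3 at 23 °C or ozs3 replicate 2 at 4 °C (adjusted p between 0.0102 and 0.0956). MTPA1 had an interaction of 1.92 ± 0.65 that was not called (adjusted p = 0.0783). It was called without Col-0 replicate 3 at 23 °C (0.00220, with up to 0.165 for other arrays left out) or with the replicate number as a block (0.0167). With all arrays and no block, 1 of 3 zinc genes was called over all probe sets and 2 adjusted over the list alone. The zinc list did not pass (camera adjusted p = 0.0791) except without Col-0 replicate 3 at 23 °C (0.00775, up to 0.130 for other arrays).

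Of the redox genes 3 of 4 had a positive interaction with either adjustment, and the list did not pass (camera adjusted p = 0.0572). Of the 3 only AT2G21640 kept its call whichever array was left out, GSTU25 was not called with an intensity trend (adjusted p = 0.103), and AT5G09570 was not called with a repeated quantile normalization (0.0637). The redox list passed without Col-0 replicate 2 at 23 °C (adjusted p = 0.00246), ozs3 replicate 3 at 23 °C (0.0227) or ozs3 replicate 3 at 4 °C (0.0481), and without dim genes (0.0459). Of the cold-regulated genes AT4G33980 had an interaction of 1.31 ± 0.26 and COR15A of −0.23 ± 0.65 (adjusted p = 0.855), and 2 members were positive and 1 negative adjusted over the list alone (list median 0.76, camera adjusted p = 0.423). Without ozs3 replicate 3 at 23 °C, COR27 was called (interaction 1.17, adjusted p = 0.00314, with up to 0.392 for other arrays left out) and the list passed (camera adjusted p = 0.00603, up to 0.941). STZ (0.90 ± 0.34, adjusted p = 0.112) was called without that array (0.0106), without Col-0 replicate 2 at 23 °C (0.0411) or with array weights (0.0251). LTI30 (−1.58, adjusted p = 0.0954) was called without ozs3 replicate 2 at 23 °C (0.0161) or with the replicate number as a block (0.0343). Of the 14 ribosome biogenesis genes 1 had a negative interaction and 3 adjusted over the list alone (camera adjusted p = 0.0791). This list passed without Col-0 replicate 2 (adjusted p = 0.0429) or ozs3 replicate 3 at 23 °C (0.0178). Of the 18 stress signalling genes 6 had a positive interaction and none a negative one, including the calmodulin-like gene CML37 (1.81 ± 0.31) and WRKY6 (1.05 ± 0.19), with a median of 0.37 (camera adjusted p = 0.00167, and adjusted p = 0.195 with an estimated correlation).

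The interaction called 2300 probe sets, 977 positive and 1323 negative, 409 of them of at least 2-fold, with 1260 named genes. Of these, 821 were called in the same direction in both genotypes, 607 of them with the larger change in ozs3, 154 were called in opposite directions, 469 were called in Col-0 alone, 849 in ozs3 alone and 7 in neither. The count was 1439 without ozs3 replicate 1 at 23 °C and 1457 without ozs3 replicate 2. With 1 common median 64.0% of 2567 calls were positive, against 42.5%.

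**Figure D3:**
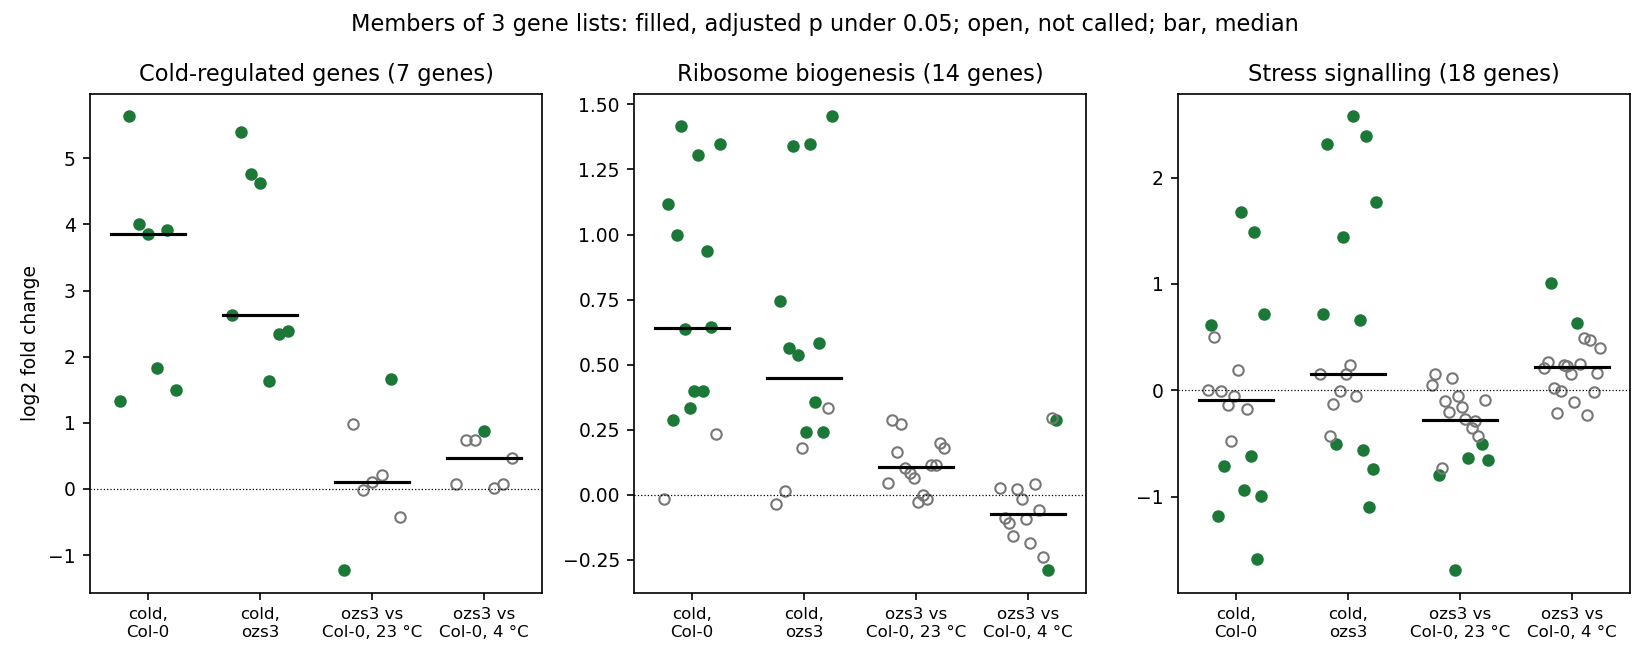
Change of each member (log2 fold change, points) of 3 gene lists in the 4 comparisons between groups, filled when called and open when not, with bars for the list medians. The medians of the 7 cold-regulated genes are 3.86 and 2.64 in the cold (means 3.15 and 3.40), and that of the 18 stress signalling genes is −0.28 for ozs3 against Col-0 at 23 °C.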

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

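Among the tests in this part, those of nearby genes, of time of day and of shoot tissue were chosen only after the result was seen. The results here stand out because the interaction, a test of the difference itself, found that the 2 genotypes responded to cold differently. AT2G41730 fell in the cold in Col-0 and rose in ozs3, with an interaction of 5.31 ± 0.52 (adjusted p = 1.45e-04). Its probe set is of the x_at type, and that of AT3G32030 below of the s_at type, so other transcripts may bind to them. The same opposite calls were made for AT1G10875 (interaction 3.44 ± 0.50), AT3G55790 (3.30 ± 0.64), AT2G21640 (2.73 ± 0.35), AT2G22880 (2.45 ± 0.23) and AT4G33666 (2.27 ± 0.37). AT2G04050 (3.29 ± 0.77) and AT2G32020 (2.83 ± 0.42) rose in ozs3 without a call in Col-0, and AT3G48450 (2.86 ± 0.26) and AT4G28460 (2.16 ± 0.55) fell in Col-0 without a call in ozs3. Between the genotypes, AT3G48450 and AT1G10875 were called at 23 °C (−2.70 and −2.44) and not at 4 °C (0.16 and 1.00). Most of these interactions thus lies at 23 °C. AT4G28460 was called at neither temperature. AT4G33666, AT2G04050 and AT2G32020 were called at 4 °C alone, and AT2G41730, AT3G55790, AT2G21640 and AT2G22880 at both in opposite directions. With an intensity trend the interaction of AT2G04050 was not called (adjusted p = 0.0689), and neither was that of AT4G28460 (0.0769). The call of AT4G28460 (adjusted p = 0.0249) also ended without replicate 1 of Col-0 at 23 °C (0.0515) or at 4 °C (0.0511), ozs3 replicate 2 at 23 °C (0.0644) or at 4 °C (0.0555), or ozs3 replicate 3 at 4 °C (0.0509).

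Opposite calls of the other kind, a rise in Col-0 and a fall in ozs3, were made for AT3G54070 (interaction −1.64 ± 0.32), AT5G02350 (−1.64 ± 0.30), the pectin methylesterase inhibitor family gene AT5G62340 (−1.71 ± 0.34) and the jacalin lectin gene AT5G49870 (−1.59 ± 0.22). AT1G66800 (−1.50 ± 0.32) rose in Col-0 alone, while AT1G54730 (−1.47 ± 0.17), the MATE efflux gene AT5G38030 (−1.81 ± 0.37) and the terpene synthase gene AT3G32030 (−1.82 ± 0.25) fell in ozs3 alone. AT3G29410 (−1.52 ± 0.25) and MSRB5 (−1.88 ± 0.22) fell in both genotypes and more in ozs3. Between the genotypes, AT3G54070, AT5G02350 and AT5G49870 were called at 23 °C (1.62, 1.28 and 1.52) and not at 4 °C (−0.02, −0.36 and −0.07). Their interactions can thus come from the difference at 23 °C alone. AT3G32030 was called at both temperatures in opposite directions, and the other genes of this paragraph at 4 °C alone. The interaction called 2300 probe sets. Of 100 drawn regroupings of the arrays, only the real one gave as many (1 of 100), and the highest other count was 1029, in a regrouping that kept the genotypes apart at 4 °C and mixed them at 23 °C. Swapping the genotypes wholly at 23 °C, which was not among those drawn, gave 2575. The regroupings break the genotype difference as well, so they do not test the interaction itself.

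Of the 6 added lists with a camera call in the interaction, stress signalling (18 genes) had a median of 0.37 (camera adjusted p = 0.00167, and adjusted p = 0.195 with an estimated correlation) and plastid-encoded genes (69) one of 0.22 (camera adjusted p = 0.00830, and adjusted p = 0.566 with an estimated correlation). Mitochondrially encoded genes (16) had a median of 0.27 (0.0271, and adjusted p = 0.566 with an estimated correlation), pseudogenes (923) 0.10 (0.00797, and adjusted p = 0.570 with an estimated correlation), and trichome birefringence-like genes (22) −0.21 (0.0130, and adjusted p = 0.566 with an estimated correlation). ER body and jacalin genes (7) had a median of −0.56 (0.0260, and adjusted p = 0.566 with an estimated correlation). Called members included NAI2 (−0.95), TBL28 (−0.73) and cox2 (0.76), and of the called pseudogenes 10 were positive and 6 negative. The plastid call ended without ozs3 replicate 2 at 4 °C (adjusted p = 0.0619). The mitochondrial call ended without Col-0 replicate 3 (0.05004) or ozs3 replicate 1 (0.0608) at 23 °C, and without Col-0 replicate 2 (0.0583) or ozs3 replicate 3 (0.0603) at 4 °C. That of the ER body and jacalin list ended without ozs3 replicate 2 at 23 °C (0.0554), or Col-0 replicate 3 (0.0596) or ozs3 replicate 1 (0.0920) at 4 °C. The other calls held whichever array was left out, and no median changed its sign with a repeated quantile normalization or 1 common median. The pseudogene median shrank to 0.03 with the quantile normalization, and in this contrast dim probe sets had a median of 0.10 and the others −0.02.

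Genes that differed between the genotypes at 23 °C lay near one another in the gene order. In the other comparisons the ratios to shuffled calls were between 1.02 and 1.11. These were smaller but also beyond chance (permutation p between 1e-04 and 0.0116), except for genes with a positive interaction (ratio 1.02, permutation p = 0.363). Nearness was thus not particular to 23 °C. The sizes of the ratios are not comparable, since a larger called share leaves less room above shuffled calls. In the cold response 2413 to 3363 genes were called per direction, against 390 and 400 at 23 °C. Genes called higher in ozs3 formed 218 pairs within 10 named genes of each other where shuffled calls gave 114 (ratio 1.91), and genes called lower 173 where they gave 120 (ratio 1.44), with a permutation p = 1e-04 in both, the smallest the shuffles can give. A chance order is thereby excluded. Weaker probe binding in ozs3 would lower signals, so it cannot make the higher genes, which follows from their direction alone. For the 229 lower genes with such a neighbour the median was −0.57 at 23 °C and −0.0929 ± 0.037 at 4 °C (standard error over genes taken as independent). At 4 °C 62 of them were still called lower and 18 were called higher. These genes were picked for their difference at 23 °C, so some shrinkage at 4 °C follows from that choice. The test made no allowance for this and cannot decide about weaker binding for the lower genes. Hybridization between neighbouring copies was tested on pairs 6 to 10 genes apart without s_at and x_at probe sets, where the ratio was 1.69 for higher genes and 1.21 for lower ones (permutation p = 0.0549), so it stays open for the lower genes. No biological explanation was tested.

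The list of 18 stress signalling genes had a median of −0.28 for ozs3 against Col-0 at 23 °C (5 called lower) and of 0.37 in the interaction (6 called positive), with camera adjusted p = 0.195 with an estimated correlation in both. These results are not independent, since the interaction is the difference at 4 °C minus that at 23 °C. A lower value at 23 °C alone makes the interaction positive. At 4 °C the list median was 0.22. With the preset correlation neither result rested on 1 array, with a largest adjusted p of 0.00766 when each was left out. A fit with the replicate number as a block (larger adjusted p = 0.00112; pair medians −0.27, −0.34 and −0.23 at 23 °C) cannot decide about a difference between numbers, since each number occurs once in every group. Time of day or handling at harvest cannot be told apart from genotype here. Only 1 gene of the clock list, GI, had a named probe set, and the list does not address handling. A milder stress state of ozs3 at 23 °C is a candidate explanation that was not tested further.

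The list medians of plastid-encoded transcripts (0.17 ± 0.021) and mitochondrially encoded ones (0.29 ± 0.083) lay above 0 for ozs3 against Col-0 at 4 °C, with 3 of 69 and 6 of 16 genes called higher (camera adjusted p = 0.566 with an estimated correlation in both). Over all probe sets 1461 of 22746 were called higher, a larger share than in the plastid list and a smaller one than in the mitochondrial list. In this paragraph ± is a standard error of the median over the genes of a list. It takes the genes as independent and holds no spread between arrays, so it does not measure how sure a shift is. Brightness alone does not account for the plastid median, which lay at percentile 100 of 10000 lists matched on brightness. These ran from −0.02 to 0.08 in their central part. The matched lists were drawn from unrelated genes and lack the correlation among plastid genes. The percentile therefore does not measure how sure the shift is either. More shoot tissue in the samples stays open. The 22 nuclear photosynthesis genes had a median of 0.0503 ± 0.051 (percentile 53.2 of their matched lists), but the 3 planned shoot genes one of 0.13 ± 0.13, with none called. A change in organelle transcripts in ozs3 in the cold is a candidate explanation, found and tested on the same data.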

How the results depend on the processing

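No test in this part was chosen after its result was seen, but the added lists and their alternatives were chosen after the annotation was read. No called gene or list reversed its direction. The medians of 29 of 160 list tests, none of them called, changed sign with a repeated quantile normalization or 1 common median, and with 1 common median the share of calls that were higher moved in every contrast, to a majority for the cold response in Col-0 (46.6% to 52.4%) and in ozs3 (48.8% to 66.1%), at 4 °C (43.9% to 60.7%) and in the interaction (42.5% to 64.0%), and from 49.9% to 41.2% at 23 °C. Counts called stayed within 1.5 times under every alternative for the cold response in Col-0 (9035 to 10786), in ozs3 (10272 to 14020), their overlap (6996 to 8220), ozs3 against Col-0 at 4 °C (2227 to 4370) and the named genes. For ozs3 against Col-0 at 23 °C the count of 1442 became 2253 with the replicate block and 2323 with array weights, which ran from 0.56 (ozs3 replicate 1 at 4 °C) to 2.22 (ozs3 replicate 2 at 23 °C), and ranged from 767 (without ozs3 replicate 2 at 23 °C) to 1551 without single arrays. The interaction ranged from 1439 (without ozs3 replicate 1 at 23 °C) to 2279 without single arrays and the overlap of genotype differences from 227 to 315, with 551 under the block. The cause of these differences was not tested. Of the 55 tests of fixed lists 5 were called, 0 with camera and an estimated correlation (3 had an unadjusted p under 0.05), 19 with fry, 6 with the block and 5 to 11 without single arrays (11 without Col-0 replicate 2 or ozs3 replicate 3 at 23 °C). The 105 tests of added lists went from 22 calls to 0 with the estimated correlation (8 with an unadjusted p under 0.05), 39 with fry, 25 with the block and 17 to 29 without single arrays. In contrasts where the numbers pair the arrays the block added 25 calls to the named genes and 1 to the lists, and it changed no other call there. In the other contrasts it added 22 and 3, with the interaction of MTPA1 (adjusted p = 0.0167) and the iron deficiency list in ozs3 (0.0307) among them. For the cold response in ozs3 the pairs correlated at 0.320, 0.0809 and 0.310, so replicate 2 lay below the limit of 0.1. All 12 arrays nevertheless correlated best with their own number, so a pairing there is not excluded. The block gave 12512 calls for the cold response in ozs3 and 3379 for the interaction. Of the 453 called among the 710 results for named genes, 402 to 427 stayed called without single arrays, and none reversed. The comparison of only the arrays compared is the same fit for the interaction. Dim signal limits 6429 probe sets, and without them the count for ozs3 in the cold was 10376.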

Other observations

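No test in this part was chosen after its result was seen, but the values of the single array below were looked at only then. Beyond the lists described above, 3 of 14 SWEET sugar transporter genes were higher in ozs3 at 4 °C, among them SWEET2 (0.94) and SWEET13 (0.64), with a median of 0.14 (camera adjusted p = 0.0338, and adjusted p = 0.566 with an estimated correlation). That call ended without Col-0 replicate 2 or 3 at 4 °C (adjusted p = 0.0873 and 0.0770) or ozs3 replicate 3 at 4 °C (0.0599). Of 7 ER body and jacalin genes 2 were lower in ozs3 at 4 °C, NAI2 (−0.68) among them, with a median of −0.39 (0.0420, and adjusted p = 0.566 with an estimated correlation). This call ended without Col-0 replicate 2 at 23 °C (0.0542), or Col-0 replicate 3 (0.111) or ozs3 replicate 1 (0.214) at 4 °C, and without dim genes (0.0619). Of 7 tubulin genes only TUA1 (−0.41) was called lower, and with the replicate number as a block TUB1 too (−0.48, adjusted p = 0.0170). The list median was −0.20 (camera adjusted p = 0.0457, and adjusted p = 0.566 with an estimated correlation). This call ended without Col-0 replicate 2 or 3 at 23 °C, Col-0 replicate 1 or 3 at 4 °C, or ozs3 replicate 1 or 2 at 4 °C (adjusted p between 0.0108 and 0.178 over all arrays left out), and without dim genes (0.134). Of 923 pseudogenes 142 rose and 11 fell in ozs3 in the cold, with a median of 0.11 (0.00797, and adjusted p = 0.569 with an estimated correlation) that shrank to 0.03 with a repeated quantile normalization. Both counts are smaller shares than those over all probe sets (5674 and 5950 of 22746). Dim probe sets had a median of 0.11 in that contrast and the others −0.05. The added lists of chaperones, tau glutathione transferases, CYP71B, GH9, beta-glucosidase, serine carboxypeptidase-like and LEA genes were not called by camera with the preset correlation on all arrays, although fry called all but the chaperones and the serine carboxypeptidase-like genes in some contrast. For ozs3 against Col-0 at 23 °C the chaperones were called with the replicate number as a block (adjusted p = 0.0280). They were called there too without Col-0 replicate 1 (0.0136), ozs3 replicate 2 (0.0152) or ozs3 replicate 3 (0.0249) at 23 °C, or Col-0 replicate 1 at 4 °C (0.0488). The serine carboxypeptidase-like genes were called there without dim genes (0.0221), Col-0 replicate 1 (0.0328) or ozs3 replicate 3 (0.0370) at 23 °C. In the interaction they were called without dim genes (0.0186) or Col-0 replicate 1 at 23 °C (0.0424).

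In ozs3 replicate 3 at 23 °C the cold-regulated genes were high, while the probe sets that respond to cold in both genotypes, taken by their medians, were not. COR15A read 7.60 there against 5.24 and 5.23 in the other arrays of that group, and COR15B 6.26 against 4.82 and 4.65. The 4168 probe sets that fell in both genotypes differed by a median of −0.02 from the other arrays. Such medians say little about single strong responders, some of which also had a wide SD in ozs3 at 23 °C, as given above. Without this array 10727 probe sets were called for ozs3 in the cold, 1299 for ozs3 against Col-0 at 23 °C, 3341 at 4 °C and 2279 in the interaction.

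Other splits of the samples were counted for each result. For the cold response in Col-0 (9987 calls), in ozs3 (11624), and ozs3 against Col-0 at 23 °C (1442) and at 4 °C (3326), the 6 arrays allow 10 splits, too few for a share under 0.05, and 1 split, the real one, gave as many calls. The highest other counts were 0, 0, 1 and 0. Among the 3 other splits that part as many pairs of equal number as the real one, the highest count was 0, and the 6 others part 1 pair. For the overlap of cold responses (7532) and of genotype differences (347), 1 of 100 drawn regroupings, the real one, gave as many, with highest other values of 0 and 1. The other regroupings called at most 0 and 1 probe sets in the comparison with fewer calls, so they could share no more, and this does not test the overlaps themselves. For the number of fixed list calls (5), 66 of 100 regroupings gave as many and the highest other number was 16. These list regroupings mix arrays of both temperatures, so the cold response can itself make list calls in them. The share therefore cannot decide about chance, which is neither excluded nor shown for the 5 calls.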
